A study of Mus musculus with 18 samples.

How the data were processed

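m6A-seq enriches RNA fragments that carry N6-methyladenosine (m6A) with an antibody and sequences them beside the unenriched input. The series holds 18 samples of mouse cells in 8 groups, an antibody-enriched and an input library for each culture. Per the labels, 3 enriched libraries came from embryonic stem cells (ESCs) kept in serum-free medium with LIF and 2 kinase inhibitors (2i), 3 from embryoid bodies (EBs) grown from ESCs for 8 to 21 days, 2 from embryonic fibroblasts (MEFs) taken at embryonic day 13.5, and 1 from Mettl3-knockout ESCs marked as a negative control. The series' design text calls the replicates of ESCs, EBs and MEFs biological. Each sample was placed in its group from its title, and replicates are named by the letters the titles give.

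The 10 files analysed hold genomic positions of peaks and, in 3 of them, gene names. They contain no score, fold enrichment, p-value or read count for any peak. Of these, 7 list the peaks of 1 enriched library each, called by the authors per library (ESC replicates A, B and C, EB replicates A, B and C, and the Mettl3-knockout library). The other 3 hold the authors' final peaks of ESCs, EBs and MEFs with a gene symbol per peak. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.10, MACS 1.4.1 and the mouse build mm10 were used, with no role, order or threshold stated; peak names in the EB and ESC library files begin with the name of a later MACS release. How replicates were joined into the final lists is not given in the sources used here. Compared with the library lists, 10419 of the 10431 final ESC peaks equalled a merged region of the 3 ESC libraries, and each overlapped at least 2 of them. All 8384 final EB peaks overlapped a peak of EB replicate C, so a final EB peak depended on that library. MEF peaks of single libraries and the input libraries were not analysed here, and a MEF value has no replicate error.

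The number of sequenced reads per library is unknown, because the files hold positions only. A longer list can come from deeper sequencing, more methylated RNA or a looser threshold. A peak also needs its transcript to be expressed, so the presence of a peak is a joint readout of expression and methylation. Peak width was used in place of the missing score, for ranks within a list only.

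Peaks were compared with the GRCm38 (mm10) sequence and the basic gene set of GENCODE release M21; no peak ended beyond a chromosome end (0 peaks). A gene had a peak in a library when at least 1 bp of a peak overlapped one of its annotated exons, without regard to strand, so that overlapping and antisense genes can share a peak. Places along mRNAs were taken from the peak centre and each gene's canonical transcript. Overlap of 2 lists meant at least 1 bp, and similarity was the Jaccard index over base pairs. For the motif, GGAC was sought on the transcript strand within 50 nt of the peak centre and in 1 random exonic window of the same gene (random seed 7). Motif shares cover only peaks centred in a canonical mRNA and at least 50 nt from its ends (7628 peaks in ESC replicate A). The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pysam 0.24.0, and figures matplotlib 3.10.9. Coordinates are counted from 1. Starts in the MEF list were read as counted from 0, like those of the other lists, which could not be checked, so MEF starts and widths may be off by 1 bp.

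ESCs and EBs were compared with 2-sided exact permutation tests over libraries, whose smallest p with 3 against 3 is 0.1. Genes called in 1 cell type needed a peak in 3 of 3 libraries of that type and 0 of 3 of the other, and the count was set beside the other splits of the 6 libraries. The knockout and the final lists have 1 list each and were described without a test between conditions. Wilson 95% intervals are given for single lists and cover counting error only. Gene lists (21 lists, 575 symbols, 573 members over all lists after joining alternative names, 0 symbols unmatched) were tested with Fisher's exact test, 2-sided, against the 16052 genes with a peak in any library or final list, with 0.5 added to each cell of the log2 odds ratio and Benjamini-Hochberg adjustment over the 21 lists within a family. The call of genes was tested on simulated data drawn for 15897 genes, where 81% of 100 seeded ESC genes and 82% of 100 seeded EB genes were recovered beside 52 and 70 unseeded calls. Seeded genes were given a high fixed rate of detection in their own cell type and were never detected in the other. Their recovery follows from that setting and is no estimate of sensitivity in the real libraries.

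The groups, the main tests, the gene lists and the rule for named genes were fixed before the data were examined. Chosen later were the shares near transcript starts and of mRNA peaks, the knockout's overlap by place, the tests over libraries of members with a peak, and the tests that the closing section names as such. That rule names Mettl3, members of the gene lists, the 12 ESC-only and 12 EB-only genes ranked highest, the 10 highest-ranked ESC genes without a knockout peak, the genes of the 10 top knockout peaks and 12 genes of the MEF list alone, leaving out unnamed gene models. It asked for the peak score, and width took its place. Settings tried were other overlaps, merged peaks, other calling rules, other windows and motifs, other backgrounds, a minimum peak width, equal numbers of peaks per library, each replicate left out and the replicate letters as pairs. Equal numbers were reached by random thinning (20 draws), since ranking by score was not possible.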

Results

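Peak lists of 7 antibody-enriched m6A-seq libraries were analysed, 3 from mouse ESCs, 3 from EBs and 1 from Mettl3-knockout ESCs, with the authors' final lists for ESCs, EBs and MEFs. ESCs in 2i and LIF represent the naive state of pluripotency. EBs are aggregates in which ESCs differentiate into derivatives of the germ layers, and MEFs are a differentiated cell type. ESC replicates A, B and C held 10515, 19816 and 17698 peaks, EB replicates A, B and C held 18185, 21509 and 12364, and the Mettl3-knockout library held 2043. These peaks fell on 6002, 10862 and 9947 genes in ESCs, on 9841, 11113 and 7481 in EBs and on 2011 in the knockout. The number of reads behind a peak is unknown, and intervals below cover counting error only.

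**Figure D1:**
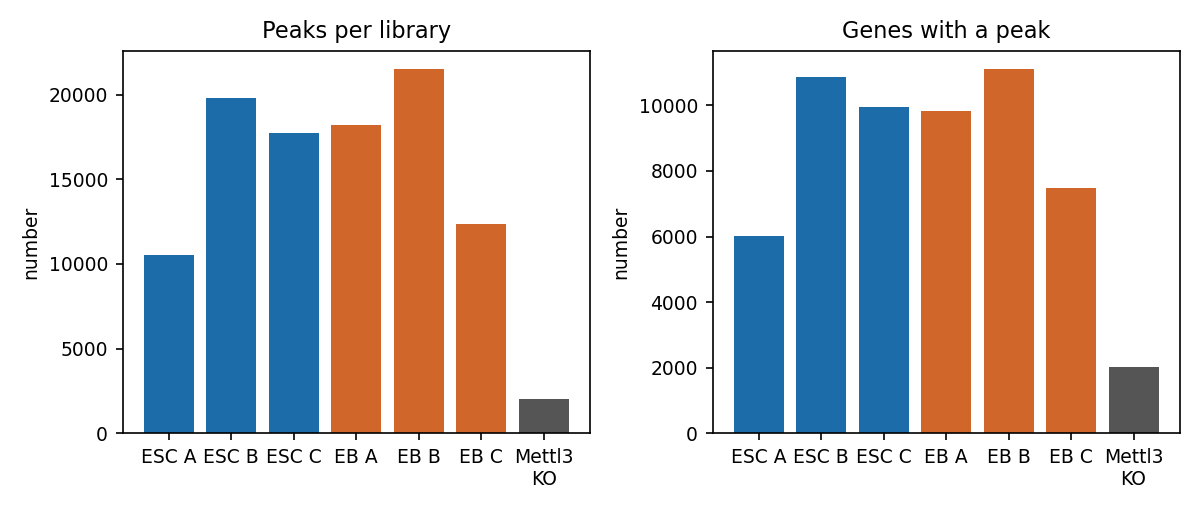
Number of peaks in each library of ESCs, EBs and Mettl3-knockout ESCs. ESC libraries lay between 10515 and 19816 and EB libraries between 12364 and 21509, against 2043 in the knockout.

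The first comparison asked which peaks depend on Mettl3, the catalytic subunit of the nuclear m6A methyltransferase. In the knockout library, peaks were few and lay at the 5′ end of transcripts, while those around stop codons and in 3′ UTRs were almost absent. Nanog, a transcription factor of the naive state, had a peak near its start and another before its stop codon in each ESC library, and its knockout peak overlapped the one near the start, with its own centre in coding sequence 233 nt from the transcript start. Sox2, another pluripotency factor, had peaks in all 3 ESC libraries and none in the knockout. The ESC mean of 16010 peaks (SD 4875, n = 3) was 7.84 times the knockout's number. Knockout peaks were also narrower, with a median width of 98 bp against a mean of 186 bp for the medians of the ESC libraries. Whether the knockout list was called with the same settings as the ESC lists is not stated, so part of both differences may come from peak calling. The Mettl3 gene itself (chromosome 14, 52294841 to 52305128) had no peak in any of the 7 libraries or 3 final lists, so the knockout label could not be checked from it.

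A knockout peak overlapped 6.16% ± 1.52 of ESC peaks (SD, n = 3 ESC libraries), with 6.38%, 7.55% and 4.54% in replicates A, B and C, and a mean of 0.865% of the 2043 widest peaks of each ESC library. When the other ESC libraries were thinned at random to 2043 peaks, they overlapped 7.49% ± 0.392, a value within the spread of the knockout's, and when cut to their 2043 widest peaks, 13.96% ± 3.72, above it. Wide peaks also cover more bases. The place of the overlapped peaks was uneven. Of ESC peaks centred within 200 nt of a transcript start, 36.5% ± 9.91 were overlapped by a knockout peak, against 1.42% ± 0.423 of the peaks further along mRNAs, 0.326% ± 0.119 of those within 200 nt of a stop codon and 0.145% ± 0.0414 of those in 3′ UTRs. Each of the 3 ESC libraries showed this order of start over stop. Of 1687 knockout peaks in mRNAs, 80.1% lay near a start (95% interval 78.2 to 82.0) and 1.72% near a stop codon (upper bound 2.46), where the ESC libraries had 14.4% ± 5.73 and 25.7% ± 3.36. The motif GGAC, the core of the usual m6A sequence, was found in 40.9% of 1616 knockout mRNA peaks. Random windows of the same genes held it in 34.3%, a gap of 6.56 percentage points against 21.3 ± 1.77 in ESCs. The knockout was a single library, with no replicate check, and 33.1%, 73.4% and 39.5% of its peaks were overlapped by ESC replicates A, B and C.

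**Figure D2:**
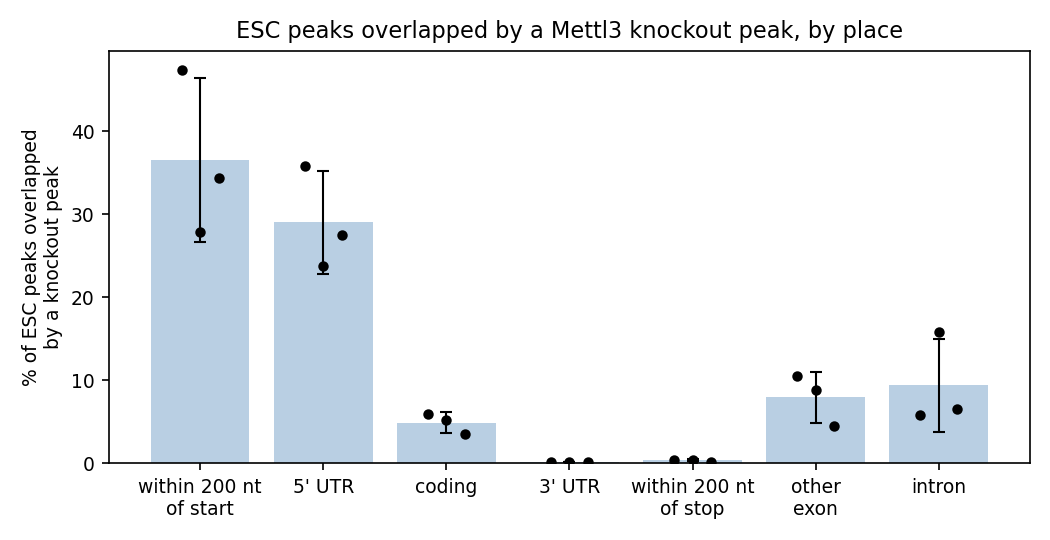
Percent of ESC peaks overlapped by a Mettl3-knockout peak, by the place of the ESC peak, with dots for ESC replicates A, B and C from left to right, bars for the mean and error bars for the SD. The mean was 36.5% within 200 nt of transcript starts and 0.326% within 200 nt of stop codons.

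Among the 40 naive and core pluripotency genes, the ESC peaks near transcript starts were overlapped by a knockout peak in 23 of 42 cases (54.8%), summed over the 3 libraries, and their other mRNA peaks in 8 of 169 (4.73%). In ESC replicate A, the start peak of Nanog on chromosome 6 (122707615 to 122707783, 5′ UTR) was overlapped by the knockout peak at 122707640 to 122707962, and the peak at 122713156 to 122713618, centred 166 nt before the stop codon, was not. Klf4, a Krüppel-like factor used in reprogramming, showed the same pattern, with a start peak on chromosome 4 (55532216 to 55532484) overlapped in the knockout and a 907 bp peak in its coding sequence (55530039 to 55530945) without one. Sox2 had in replicate A a 1040 bp peak on chromosome 3 (34650723 to 34651762) that spans its stop codon region. A knockout peak was present in 9 of 20 naive pluripotency genes (45%, 25.8 to 65.8), among them Esrrb, Klf2, Tbx3 and Zfp42, and in 6 of 20 core genes, among them Dnmt3l, Mycn and Gdf3. The list of glycolysis and respiration had 16 of 32 members with a knockout peak (50%, 33.6 to 66.4), including Hk2, Ldhb and Pgk1, and the ribosomal proteins 1 of 71, Rpl31. No member of the endoderm, mesoderm, Hox or blood lists had one. Few of their members had a peak in all 3 ESC libraries (2, 1, 1 and 1, and 0 of the ribosomal proteins), so these absences say little about the knockout. Of all genes with a peak in all 3 ESC libraries, 19.9% had a knockout peak. Among such genes it was 6 of 13 naive, 3 of 12 core and 4 of 6 glycolysis and respiration genes. Other lists varied as well, with 6 of 11 cell cycle genes, 5 of 14 apoptosis and p53 genes and 2 of 24 Polycomb and Trithorax regulators.

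Of 5156 genes with a peak in all 3 ESC libraries, 4130 had no knockout peak and 1026 had one (19.9%, 18.8 to 21.0). Widest among the genes without a knockout peak were Flg, which encodes filaggrin, and Arid1a, a subunit of the BAF chromatin remodelling complex, whose widest peak averaged 1667 bp ± 66.1 (SD, n = 3) and covered coding sequence on chromosome 4 from 133680235 to 133681977 in the widest form. The Wnt receptor gene Fzd5 (1237 bp ± 88.6), Znrf3, an E3 ligase that removes Wnt receptors (1259 bp ± 266), and Mesd, a chaperone of Wnt co-receptors (1130 bp ± 198), were also among the 10, as were Hs6st1, Irf2bpl, Taf5l and Arid1b, the paralogue of Arid1a (1103 bp ± 34.6). Rbm15, an RNA-binding partner of the m6A writer complex itself, had a coding peak of 1246 bp ± 89.5 on chromosome 3 (107331146 to 107332446). All 10 had their peak in the coding sequence except Mesd, in its 3′ UTR, and Flg, whose peak centre lay in an intron and in no annotated exon. The link of that peak to Flg rests on exon overlap elsewhere in the peak.

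The widest knockout peak was an exception to the position at starts. It lay in the 3′ UTR of Mat2a, which encodes the enzyme that makes S-adenosylmethionine, on chromosome 6 from 72432828 to 72433455 (628 bp), and ESC replicates A, B and C had peaks of 518, 507 and 449 bp at the same place. The other wide knockout peaks were at most 324 bp and belonged to Tnc (tenascin C), Nanog, the nuclear long non-coding RNA Malat1, Dnmt3l, the histone gene Hist1h1c, Atpif1, Tma7, a region shared by Atf5, Il4i1 and Nup62, and Col6a1.

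EBs and ESCs were then compared to ask how m6A peaks differ once pluripotent cells differentiate. Most genes with a peak in every library of one cell type also had one in the other. Of 5156 genes with a peak in all 3 ESC libraries, 5108 had a peak in at least 1 EB library, and of 6373 genes in all 3 EB libraries, 6252 had one in ESCs. Both sets hold the 4509 genes with peaks in all 6 libraries, 4273 of them protein-coding, among them Sox2, Nanog, Klf4 and Esrrb. EB libraries held 1343 more peaks on average (16010 ± 4875 against 17353 ± 4629, n = 3 and 3, exact permutation p = 0.6), less than the spread between replicates. This difference turned to -1404 without ESC replicate A and to -735 without EB replicate B.

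Libraries of one cell type were not clearly closer to each other than to the other type. The mean Jaccard index was 0.361 for ESC pairs, 0.458 for EB pairs and 0.388 between ESCs and EBs. Between ESCs and the knockout it was 0.0258. The knockout list covered 0.215 Mb against an ESC mean of 3.68 Mb, so this index was held low by list size however its peaks lay. Pairs within a type exceeded pairs between types by 0.0218 (exact permutation p = 0.2 over 10 splits), which fell to 0.00457 with libraries thinned to equal numbers (exact permutation p = 0.8), and the split that set apart ESC replicate B with EB replicates A and B, the 3 longest lists, gave 0.0421. Without EB replicate A or B the difference was -0.0151 or -0.0152.

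Along transcripts, coding sequence was the part in which EBs stood above ESCs in every library. Peaks centred in coding sequence made up 41.6% ± 2.19 of ESC peaks (SD, n = 3) and 50.4%, 49.4% and 50.3% of the peaks of EB replicates A, B and C (SD 0.543), a difference of 8.41 percentage points with no overlap between the groups (exact permutation p = 0.1, the smallest possible). ESC replicate A had 13.1% of its peaks between genes, against 0.464% and 0.938% in replicates B and C and 0.391% ± 0.0125 in EBs. The 3′ UTR share of all peaks was 28.4% ± 3.70 in ESCs and 26.3% ± 1.96 in EBs (exact permutation p = 0.5), a difference of -2.09 points that fell to -0.0154 without ESC replicate C. Over peaks in mRNAs alone, a choice made after seeing the data, the coding share was 51.8% ± 2.14 in ESCs and 56.4% ± 0.599 in EBs, and the 3′ UTR share 35.3% ± 4.38 and 29.6% ± 1.83, each with exact permutation p = 0.1. Stop codons carried 25.7% ± 3.36 of ESC mRNA peaks and 23.3% ± 1.98 of EB mRNA peaks within 200 nt (exact permutation p = 0.4). This difference of -2.43 points ran from -0.737 (without ESC replicate A) to -4.09 (without ESC replicate B) with 1 library left out. Near starts the shares were 14.4% ± 5.73 and 16.0% ± 2.25 (exact permutation p = 0.6), a difference that turned to -0.429 points without ESC replicate C. With 11 parts tested, none could pass an adjustment for multiple tests in this design.

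**Figure D3:**
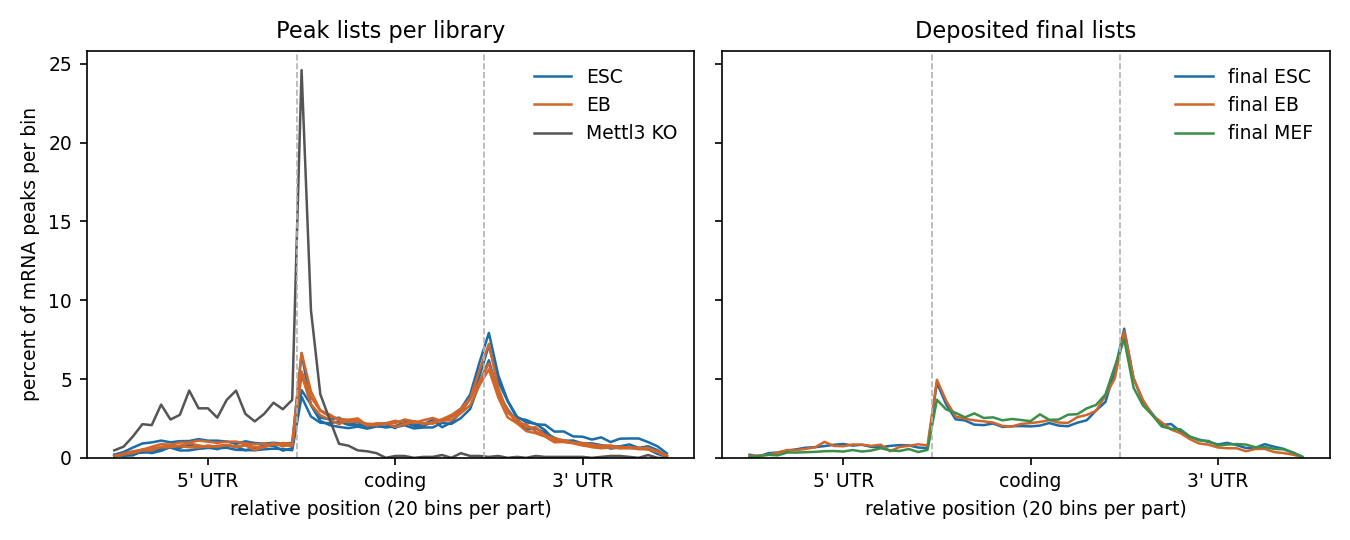
Percent of mRNA peaks per bin along the 5′ UTR, coding sequence and 3′ UTR, each divided into 20 bins, for single libraries on the left and the authors' final lists on the right. Peaks of ESCs and EBs gather around the stop codon, within 200 nt of which lay 25.7% and 23.3%, and those of the Mettl3 knockout near the start (80.1%). ESCs and EBs have a second maximum in the first bin of the coding sequence, the highest bin in ESC replicate B (6.64%) and EB replicate B (6.66%).

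Peaks of both cell types carried the m6A motif. GGAC lay within 50 nt of the centre of 56.4% ± 2.39 of ESC mRNA peaks and 54.6% ± 3.50 of EB mRNA peaks. It lay in 35.1% ± 0.649 and 34.6% ± 0.296 of random windows. The excess over random windows was 21.3 points ± 1.77 in ESCs and 18.2, 17.5 and 24.3 points in EB replicates A, B and C (difference of means -1.28, n = 3 and 3, exact permutation p = 0.6), less than the spread between replicates. With 1 library left out the difference ran from -0.0349 (without EB replicate B) to -3.44 (without EB replicate C). With DRACH (D is A, G or T, R is A or G, H is A, C or T) in place of GGAC, the excess was smaller in both cell types. Its values are given in the section on processing.

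A small set of genes had peaks in 1 cell type alone. Peaks in all 3 EB libraries and in no ESC library were found for 121 genes, 106 of them protein-coding, and the reverse for 48 genes, 32 of them protein-coding and 9 microRNA gene models. EB-only genes included Apob and Apoa1, apolipoproteins of endoderm derivatives such as liver and yolk sac, Spry4, a feedback inhibitor of FGF and MAPK signalling, and the Notch ligand Dll1. None of the 21 gene lists had a member among the ESC-only genes. On simulated data the same call gave 52 ESC-only and 70 EB-only genes that had not been seeded, so the 48 ESC-only genes are no more than that number, and single genes named below are not secure. The numbers are also open to the grouping, since 4 of the 10 splits of the 6 libraries gave at least the 169 genes of the real one. The other splits reached 482, with 480 of these genes on the side of the 3 longest lists.

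The widest EB-only peak was that of Spry4, which averaged 1052 bp ± 459 (SD, n = 3) in the 3′ UTR on chromosome 18, reaching from 38588986 to 38590563. Apob had peaks of 424 bp ± 51.4 in coding sequence (chromosome 12, 8008829 to 8009310) and Slc40a1, the iron exporter ferroportin, of 412 bp ± 57.5 (chromosome 1, 45910944 to 45911416, coding). Dll1 peaks averaged 309 bp ± 102 in the 3′ UTR (chromosome 17, 15367634 to 15368022). Frzb, a secreted Wnt antagonist, the axon guidance gene Sema3a, Mdfi, an inhibitor of myogenic transcription factors, and the lysophosphatidic acid receptor gene Lpar3 were in the same set, with Tpbgl, Cobll1, Kirrel2 and Chkb, whose peak also lies in an overlapping gene. All 12 were in the authors' final EB list and in neither of the other final lists. Peaks of the final ESC and EB lists overlapped those of the libraries used for these calls. They therefore give no independent check on the EB or the ESC side. On the ESC side, Tnfrsf22, a decoy receptor of the TNF family, had peaks of 512 bp ± 176 in the 3′ UTR on chromosome 7 (143635644 to 143636338). Others were the caudal homeobox gene Cdx1 (216 bp ± 74.3), Eya1, a transcriptional coactivator (227 bp ± 24.0), the interferon-induced kinase gene Eif2ak2 (278 bp ± 145), the monoamine oxidase gene Maoa (284 bp ± 203) and Polr2g, a subunit of RNA polymerase II (217 bp ± 70.6), beside Zfp488, Pramef17, Efr3a, Adap2, Cep112it and Cd3eap. Of these 12, Pramef17 and Cep112it were absent from the final ESC list, none was in the final EB list, and Eya1, Eif2ak2 and Cd3eap were also in the final MEF list. With a peak in at least 2 of 3 libraries and 0 of 3 of the other type, 519 genes were ESC-only, among them Prdm14 and Mettl14, and 634 EB-only, among them Hand1, Tal1, Cdh5 and Lefty1. Single libraries moved the strict counts: the ESC-only count was 436, 88 and 91 without ESC replicate A, B or C and 83 and 115 without EB replicate A or B, and the EB-only count 483 and 237 without ESC replicate B or C and 214 and 494 without EB replicate A or C.

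Of the germ layer lists, endoderm was the one whose values did not overlap between the cell types, and no list passed the test over libraries. Of 20 endoderm genes, 15.7 ± 2.52 had a peak in an EB library and 8.33 ± 4.73 in an ESC library (SD, n = 3 each, exact permutation p = 0.1, adjusted 0.84 over 21 lists), with no overlap between the groups. Foxa2, a pioneer factor of endoderm, Lama1, Col4a1 and Col4a2 had peaks in all 3 EB libraries and 1 of 3 ESC libraries, while Gata4 and Sox17 had them in all 6. Imprinted genes were the other list without overlap (16 of 27 in each EB library against 13.3 ± 1.15, exact permutation p = 0.1, adjusted 0.84), with Impact in 3 EB libraries and 1 ESC library. Chance gives such a separation to 10% of lists with 3 against 3, and 2 of 21 showed it. Naive pluripotency genes had peaks in 16.3 ± 2.08 and 15.3 ± 1.15 of 20 members in ESCs and EBs (exact permutation p = 0.6), and core pluripotency genes in 15.3 ± 2.08 and 17.7 ± 0.577 of 20 (exact permutation p = 0.2). Mesoderm genes had 4 ± 2.65 and 7 ± 3.61 of 21, and neural genes 6.67 ± 2.52 and 6.33 ± 0.577 of 20. Between ESC-only and EB-only genes, Fisher's exact test with Benjamini-Hochberg adjustment called 0 lists, with 0 at an unadjusted p under 0.05.

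**Figure D4:**
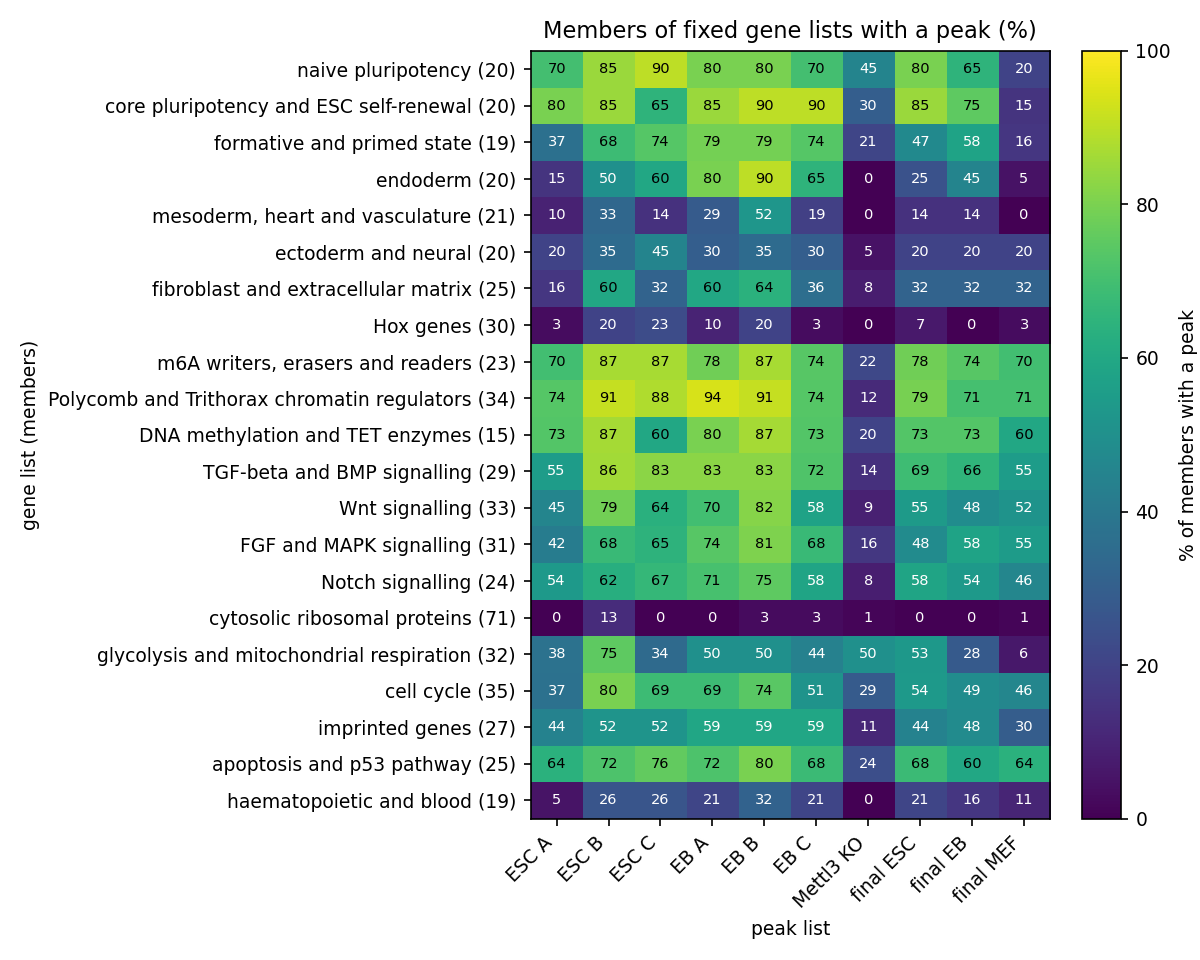
Heat map of the percent of members with a peak, for each of 21 gene lists (vertical) in each library and final list (horizontal). Endoderm genes range from 3 to 12 of 20 members in ESC libraries and from 13 to 18 in EB libraries, and Hox and ribosomal protein genes are low throughout.

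Within ESCs, the regulators of pluripotency and chromatin carried peaks more often than other genes. Against the same background these lists were also called in EBs, as given under other observations. A peak in at least 2 of 3 ESC libraries was found for 17 of 19 naive pluripotency genes with any peak (89.5% against 51.8% of other genes, log2 odds ratio 2.71, Fisher's exact test with Benjamini-Hochberg adjustment over 21 lists, adjusted p = 0.00459), including Nanog, Esrrb and Tbx3, and for 17 of 20 core genes (log2 odds ratio 2.22, adjusted p = 0.0101), where Pou5f1, which encodes Oct4, had none in ESCs. Polycomb and Trithorax regulators had 29 of 33 (2.61, exact test, adjusted p = 0.000320), with Jarid2, Suz12, Kmt2d and Cbx7 in all 6 libraries and Ezh2, the Polycomb methyltransferase, in none. The m6A machinery was itself marked in 19 of 22 genes (2.38, exact test, adjusted p = 0.00459), among them the demethylase genes Fto and Alkbh5 and the reader genes Ythdf1 and Ythdf2. TGF-β and BMP signalling had 23 of 28 (1.99, exact test, adjusted p = 0.00459), with Smad3, Smad7 and Ski, Notch signalling 15 of 18 (2.04, adjusted p = 0.0245), with Jag1 and Hes1, and apoptosis and p53 genes 18 of 23 (1.65, adjusted p = 0.0307), with Trp53 and Mdm2. Ribosomal protein genes were the opposite, 0 of 10 (-4.50, exact test, adjusted p = 0.00459), but these are few of the 71 members, and 9 had a peak in ESC replicate B and 0 in replicates A and C, so that most entered the test through a single library. Of the remaining lists, Hox genes had 3 of 14 (exact test, adjusted p = 0.0703), and 13 lists in all did not pass. Against protein-coding genes with a peak alone, Notch signalling (exact test, adjusted p = 0.0791) and apoptosis and p53 genes (adjusted p = 0.130) did not pass, and Hox genes did (adjusted p = 0.0359). Without ESC replicate B, 5 lists passed, the ribosomal proteins not among them (exact test, adjusted p = 0.0855), and the naive pluripotency, m6A and Polycomb lists passed without any 1 of the 3 ESC libraries. These shares depend on which genes the cells express.

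The authors' final lists set ESCs and EBs beside MEFs, a fully differentiated cell type. Peaks on the same 3941 genes were found in all 3 lists, 45.9% of the 8592 genes with a final peak in any. Naive pluripotency genes had a final peak in 16 of 20 cases in ESCs, 13 in EBs and 4 in MEFs, those 4 being Klf2, Klf4, Klf5 and Tbx3, and core pluripotency genes in 17, 15 and 3 of 20. The final lists held 10431 ESC, 8384 EB and 10167 MEF peaks on 6864, 5939 and 5761 genes. EB peaks overlapped the ESC list in 79.7% of cases (95% interval 78.8 to 80.5) and ESC peaks the EB list in 69.0% (68.1 to 69.9). ESC and MEF peaks overlapped less, 59.7% of ESC peaks (58.7 to 60.6) and 64.5% of MEF peaks (63.6 to 65.4). Peak widths differed between the final lists, with medians of 284, 363 and 209 bp in ESCs, EBs and MEFs and minima of 108, 114 and 3 bp. Overlap depends on width, so the lower overlap with MEFs cannot be put down to cell type alone.

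Against all genes with a peak, 6 lists passed in the MEF list (Fisher's exact test, Benjamini-Hochberg adjustment over 21 lists). Polycomb and Trithorax regulators (24 of 33, log2 odds ratio 2.21, exact test, adjusted p = 0.000548), the m6A machinery (16 of 22, 2.18, adjusted p = 0.00563) and apoptosis and p53 genes (16 of 23, 1.98, adjusted p = 0.0109) were marked more often than other genes. Endoderm genes (1 of 19, Sparc, -2.79, exact test, adjusted p = 0.0142), mesoderm genes (0 of 13, -3.92, adjusted p = 0.0217) and genes of glycolysis and respiration (2 of 25, Hk1 and Hk2, -2.40, adjusted p = 0.0142) were marked less often. These shares depend on which genes MEFs express, and the background includes genes with peaks only in ESC or EB libraries. A low share can therefore reflect absent transcripts. Markers of fibroblasts and matrix had 8 of 18, among them Pdgfrb, Twist1 and Lox, and did not pass (exact test, adjusted p = 0.545). Coding sequence held 55.2% of MEF, 52.2% of EB and 49.0% of ESC final peaks, and 7.19% of MEF mRNA peaks lay near a start against 13.6% of ESC mRNA peaks.

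MEFs alone had a final peak on 946 genes, of which 87 had no peak in any ESC or EB library. With a peak in at least 2 of 3 libraries in place of the final ESC and EB lists, 330 genes were left to MEFs alone. Ranked by width, the 946 genes were led by Irf2bpl (1879 bp, chromosome 12, 86881507 to 86883385, coding), which had peaks in all 3 ESC libraries though not in the final ESC list. Next came Il17ra, the interleukin 17 receptor (1233 bp, chromosome 6, 120481225 to 120482457, coding), and Srcap, the catalytic subunit of a histone exchange complex (1190 bp, chromosome 7, 127559391 to 127560580, coding). Tnfaip8l1, Wbp1l, Zbtb14, B3gnt9, Soga1, Cep170b, Mtcl1, Elmsan1 and the protocadherin gene Pcdhga10 followed with 1151 to 940 bp. One final list per cell type carries no replicate error, so these differences were not tested between cell types.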

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

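The test for residual methylation in the knockout was chosen after its result was seen, the comparisons of starts with other sets of genes were not set in advance, and the other tests were set before. Knockout peaks gathered at transcript starts (80.1% of mRNA peaks). Residual Mettl3-dependent methylation or wild-type RNA as the source of most knockout peaks was argued against, since 1.72% of knockout mRNA peaks lay near a stop codon, below every ESC library. With 80.1% near starts this low share was largely fixed, so it is the same observation and no separate test. A short list of the peaks called in every library was also argued against, since those lay near a start in 7.43% of cases. Whether a short list of the strongest peaks is the cause was left open by width (-14.1 points, widest minus all), because the width of a start peak is limited by the end of the transcript. GC-rich starts (median GC of the first 200 nt differing by -0.5 points, bootstrap interval -1 to 0.5, from ESC genes without a knockout peak) and cap-adjacent dimethyladenosine at transcripts starting with A (1.25 points more A, -1.54 to 3.99, Fisher's exact test p = 0.380) cannot be told apart, as neither interval excludes 0. Other sets of genes did not settle it. A was 2.60 points less frequent than in genes with an ESC start peak and no knockout peak (-6.84 to 1.404, Fisher's exact test p = 0.215), which had a median GC of 66.5%. It was 12.2 points less frequent than in genes with no peak (-14.8 to -9.56, Fisher's exact test p = 4.98e-18). Their median GC was 52%, against 65% in genes with a knockout start peak. ESC genes without a knockout peak (25.4% A, median GC 65.5%) differed from genes with no peak (38.8% A) in the same way. These contrasts therefore decide nothing about the knockout, and whether genes with no peak are expressed is unknown. The first base was that of the annotated transcript throughout, which need not be the base where transcription starts. The loss of Mettl3, the design's own difference, stays among the open explanations.

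The 169 genes called in 1 cell type were matched or exceeded in 4 of the 10 splits of the 6 libraries, the real one included, with 482 the highest other. These 10 splits are too few for a share under 0.05. That highest split sets the 3 longest lists, ESC replicate B (19816 peaks) with EB replicates A (18185) and B (21509), against the 3 shortest, and 480 of its 482 genes lay on the side of the longest, so it points to a structure of the samples that goes with list length. Thinning to equal numbers took its excess over the real split from 313 genes to 38.5 (SD 21.5 over 20 draws), so most of the excess went with the number of peaks. The remainder exceeds its SD, the mark set in advance. That SD covers the random draws and not differences between samples, so whether the number of peaks is the whole cause stays open. Random thinning also does not remove differences in depth. Peaks near starts were argued against as the whole cause, because without them it called 346 genes against 160. No biological explanation was tested.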

How the results depend on the processing

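Choices made after seeing the data were the share near transcript starts, the minimum width of 150 bp, random thinning, the widest ESC peaks, leaving out start peaks, mRNA peaks alone, random windows from the same part, protein-coding genes with a peak as background and all tests on lists in EBs. Filters on a score of at least 100, ranking by score and the top part of the final lists by score were not run, as the lists hold no score. Over 25 results and 156 alternatives, 127 values stayed within their spread or on the same side, 23 moved and 6 reversed. A test over libraries counted as stayed whenever its sign held, since its p could not fall below 0.05. The difference in peak number (1343) was -57.7 with peaks of at least 150 bp and -1404 to 3837 with 1 library left out (-735 without EB replicate B); the Jaccard difference ran from -0.0152 to 0.0637 (-0.0151 without EB replicate A) and the share near starts from -0.429 to 4.86 points. The cause was not tested. With 1 library left out the ESC-only count ran from 58 to 436 and the EB-only count from 132 to 494, and with 2 of 3 libraries they were 519 and 634, as each asks for fewer libraries. Thinning gave 74.8 ESC-only genes. Of the widest ESC peaks, 0.865% were overlapped by the knockout. At 50% overlap, MEF peaks overlapped 58.7% of ESC peaks, and ESC peaks 63.0% of MEF peaks; MEFs alone had 330 genes when 2 of 3 libraries replaced the final lists. The GGAC excess became 5.50 points in ESCs and 4.31 in EBs with DRACH, and 18.5 in ESCs with windows from the same part; the causes were not tested. With all protein-coding genes as background 13 lists passed in ESCs and 13 in MEFs, without single ESC libraries 5 to 8 passed in ESCs, and with protein-coding genes with a peak 4 of 14 in EBs. Changes of coding share stayed between 7.43 and 9.59 points without single libraries. Whether the replicate letters pair the samples was left undecided. Deviations of same-letter ESC and EB libraries correlated across genes at -0.0123, 0.0721 and 0.0506 for A, B and C. B and C, not A, correlated best with their own letter. With the letters as a replicate block the peak number difference stayed 1343 (exact paired permutation p = 0.75, smallest possible 0.25). The block changed no call in 11 results, but it could not have done so. Its smallest p lies above 0.05, and the gene calls and their list tests are the same by definition. Unknown read depth limits every count of peaks and every absence of a peak.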

Other observations

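The test of the Mat2a motif was set before its result was seen, and the values on long exons, non-coding RNAs, EB lists, repeats and unplaced sequences were chosen after looking at the data. Long internal coding exons carried most peaks of internal coding exons. Exons of at least 400 nt held 82.5% ± 4.49 of these peaks in ESCs (SD, n = 3) against 45.8% ± 1.62 of random positions in internal coding exons of the same genes, and 71.4% ± 10.1 in EBs against 41.3% ± 3.14, a difference between cell types of -11.0 points (exact permutation p = 0.3). In the final lists the shares were 88.3% in ESCs, 85.5% in EBs and 89.6% in MEFs. In the knockout, 4 of 166 such peaks lay in a long exon (2.41%, 0.941 to 6.03), near the random share of 3.01%. Across libraries the share rose with the width of the narrowest peak in the list. That width was 77 bp in the knockout, 93 bp in EB replicate B (63.0%) and 142 bp in ESC replicate A (87.4%). Whether a width limit in peak calling favours long exons was not tested, so these differences cannot be put down to the cells alone.

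Among long non-coding RNAs with peaks in all 6 wild-type libraries and none in the knockout, imprinted Meg3 had 2 peaks in each library, and Lncenc1, an ESC transcript, had 3 in each ESC library and 1 in each EB library. In EBs, Fisher's exact test with Benjamini-Hochberg adjustment called 14 of the 21 lists at a peak in at least 2 of 3 libraries. Among these were Polycomb and Trithorax regulators (31 of 33, log2 odds ratio 3.23, exact test, adjusted p = 8.46e-05), Notch signalling (17 of 18, 3.12, adjusted p = 0.00978), FGF and MAPK signalling (24 of 29, 1.73, adjusted p = 0.0126) and endoderm genes (16 of 19, 1.81, adjusted p = 0.0367), while Hox genes had 2 of 14 (-2.75, adjusted p = 0.00978). Core pluripotency genes (18 of 20, 2.46, exact test, adjusted p = 0.0101) and naive pluripotency genes (16 of 19, 1.81, adjusted p = 0.0367) were also among the 14. Against protein-coding genes with a peak alone, 4 lists passed, the Polycomb and Trithorax, Notch, Hox and ribosomal protein lists, the last with little weight, since 9 of its 10 members in the test had a peak in ESC replicate B and most entered through it. FGF and MAPK signalling (exact test, adjusted p = 0.0870) and endoderm genes (adjusted p = 0.138) did not pass.

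Intergenic peaks set ESC replicate A apart. It had 1338 on the main chromosomes, of which 2.99% were overlapped by another wild-type library and 80.3% of the bases were soft-masked repeats, against 92 peaks, 72.8% and 17.5% in ESC replicate B. ESC replicate C had 166, with 25.3% overlapped and 67.5% soft-masked. ESC replicate A also held 37 peaks outside chromosomes 1 to 19, X and Y, which its total of 10515 includes, against 1 in the knockout; 32 of them lay on 1 unplaced scaffold and 2 on the mitochondrial chromosome.

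A candidate explanation for the Mat2a peak in the Mettl3 knockout is another methyltransferase, Mettl16, that uses the nonamer UACAGARAA (R is A or G) and is known to methylate Mat2a mRNA there. The 2 knockout peaks in the Mat2a 3′ UTR held 5 of its 6 nonamers, 4 in the peak of 628 bp and 1 in a peak of 77 bp at 72434227 to 72434303 on chromosome 6. The Mat2a peaks of each ESC library held 4 and those of each EB library 5, so the nonamer does not set the knockout apart, and of the other 18 knockout 3′ UTR peaks 0 held it (upper bound 17.6%). The hypothesis stays open, since the gene that prompted it cannot test it, and no Mettl16 loss was measured here.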
